A study of Mus musculus with 4 samples.

How the data were processed

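RNA sequencing measured the polyadenylated transcripts of cultured fibro-adipogenic progenitors (FAPs), the Sca1-positive mesenchymal cells of mouse skeletal muscle. The 4 libraries were 2 of miR-206 knockout (KO) cells and 2 of wild-type C57Bl/6 cells. Per the labels' protocols, sorted cells were expanded in a rich growth medium with FGF and then kept for 48 hours in DMEM with horse serum before RNA was taken, and libraries were made with a stranded mRNA kit. The submitters' processing notes name FastQC, kallisto and the mouse build mm10. Their versions, the annotation release, the use of strand and the step from transcripts to genes are not given in the sources used here. kallisto divides reads that match several transcripts among them by likelihood, so near-identical genes can exchange reads.

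The authors' deposited sheets held 3 kinds of values. Estimated counts per gene, as the authors deposited them, were not normalized, and between 30.5% and 35.0% of a library's genes had a count more than 0.001 from a whole number. TPM values, a depth- and length-scaled measure that the authors deposited beside the counts, summed to between 907609 and 922339 per library, less than the full sum that TPM has over all quantified transcripts. A further deposited sheet of 12078 genes held genotype means of TPM, their log2 and the log2 difference of KO over wild type. In that sheet the authors had written a genotype mean under 1 TPM as 0 and its log2 as 0, a rule that held for each of its 12078 genes. Of 13243 genes with a genotype mean of at least 1 TPM, 1165 were not in that sheet, and 1055 of these had names of the Gm or Rik kind. A list of 1675 transcription factor names carried the authors' deposited log2 fold difference for 882 of them.

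Spreadsheet software had turned 27 gene names into dates, and these were restored through the transcript beside each. Of 28649 genes, 28335 were matched by transcript to GENCODE M21, the annotation of GRCm38 (mm10), and 28529 by transcript or symbol. Coordinates are from that annotation, counted from 1. The longest annotated 3' UTR of each of 20597 genes was searched for the miR-206 seed site, as an 8mer (ACATTCCA) or as either 7mer (ACATTCC or CATTCCA). Mir206, Mir133b and Lincmd1 were not analysed here.

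Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with robust estimation, TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment over 14507 genes. The threshold was an adjusted p of 0.05, two-sided. A gene counted as changed 2-fold at an absolute log2 fold change of at least 1. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. Levels are CPM, counts scaled to the TMM-adjusted library size, as mean ± SD over 2 libraries. The 33 gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. An estimated correlation and the fry test were run beside it. Ratios of genes near 0 in the wild type carry exact 95% intervals from summed counts, which cover counting error only.

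Total estimated counts were 35521839 and 30550235 in the KO libraries and 34827986 and 44561117 in the wild-type libraries. Replicates of a genotype differed by far more than sampling noise: the chi-square per gene was 38.5 over 14088 genes for the KO pair and 29.0 over 14351 genes for the wild-type pair, where 1 is the value of sampling noise alone. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

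The fit was tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes, in a step of 14271 genes. It called 7 of 50 genes changed by 0.5 log2, 30 of 49 changed by 1, 39 of 47 changed by 2 and 48 of 50 changed by 3, each with the right sign. It also called 27 of 14075 unchanged genes. These were 17.9% of its 151 calls, above the nominal share of 5%, so in this simulation the adjusted p-values of 2 libraries against 2 were too small. On simulated lists, 0 of 30 lists of 25 unchanged genes were called by camera. Those genes were drawn independently, so this does not test the preset correlation, and estimated correlations in the real lists reached 0.928.

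Lists, tests, alternatives and the rule for named genes were chosen before the data were examined, unless a sentence says otherwise. The rule took Mir206, Mir133b and Lincmd1 where listed, Runx1, and the 10 largest positive and 10 largest negative fold changes among changed genes of at least 5 mean CPM whose KO libraries both lay on the same side of both wild-type libraries, leaving out predicted genes. It also took up to 4 changed members of each list, or its 2 members of highest mean CPM where none changed, and the 6 transcription factors of smallest adjusted p. Rps3a1, Des, Adipoq, Fabp4, Pparg, Ifit1, Ifi27, Asb5, Asb2 and Ankrd1 lie outside it and were chosen after their values were seen. Alternatives were DESeq2 size factors, upper-quartile scaling, library size alone, no low-count filter, a filter at 5 CPM, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and on log2(TPM + 0.1), edgeR without robust estimation, a replicate block, and leaving out each library in turn. A fit without a library has less power, so a call lost there need not rest on that library. A fit with each library's mean log2 CPM of muscle-lineage genes as a covariate was added after the data were seen.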

Results

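The data were RNA-seq profiles of cultured mouse FAPs, the progenitors from which muscle fat and scar tissue arise, from miR-206 KO and wild-type mice, with 2 libraries per genotype. miR-206 is a muscle microRNA whose gene, Mir206, lies on chromosome 1 from 20679010 to 20679082 on the plus strand of mm10, with Mir133b downstream from 20682769 to 20682887. Mir206, Mir133b and the host transcript Lincmd1 were not analysed here, so the genotype labels have no check from the targeted gene. Library totals ran from 30550235 to 44561117 estimated counts. The comparison asked how the transcriptome of cultured FAPs differs between miR-206 KO and wild-type cells. The labels name the strain of the wild type but not the background of the KO mice. A strain difference, if there was any, could not be told apart from loss of miR-206 in the changes below.

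The genes that rose most in KO cells fell into a group that was nearly off in the wild type and a group that rose 2-fold to 3-fold. Ifi202b, an interferon-inducible gene of the Ifi200 family, had 78.3 ± 3.17 CPM in KO (SD, n = 2) against 0 and 0.0448 CPM in the wild-type libraries, from 5105 counts against 2, a ratio of 3150 with a 95% counting interval of 872 to 26000. Rps3a2 and Rps3a3, both annotated as processed pseudogenes of the ribosomal protein gene Rps3a1, had 244 ± 2.87 and 87.1 ± 5.74 CPM in KO against 0.241 ± 0.102 and 1.25 ± 0.339 in wild type. Rps3a1 itself fell from 833 ± 41.2 CPM to 534 and 499 CPM in the KO libraries, a log2 fold change of -0.69 (SE 0.08). A processed pseudogene can share reads with its parent gene, and members of the Ifi200 family can share reads with each other, so the division of counts among them is uncertain. Their sequences were not compared. Ifi202b, Rps3a2 and Rps3a3 were called in each of the 4 fits that left out a library, and Rps3a1 in 0 of them (edgeR adjusted p of 0.124, 0.176, 0.0827 and 0.12 without KO replicates 1 and 2 and wild type replicates 1 and 2).

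Among genes with ample reads in both genotypes, Il33, an alarmin cytokine made by FAPs, rose from 59.0 ± 1.35 to 138 ± 3.98 CPM, a log2 fold change of 1.22 (SE 0.07, adjusted p = 0.00269 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ltbp1, which holds latent TGF-beta in the matrix, rose by 1.07 log2 (SE 0.07), from 190 ± 4.14 to 401 ± 11.4 CPM. The zinc and iron transporter gene Slc39a14 rose by 1.18 log2 (SE 0.10), from 139 ± 16.1 to 315 ± 17.2 CPM. Fetub, Angptl1 and the potassium channel genes Kcnma1 and Kcnj15 rose by 1.44, 1.58, 1.56 and 1.61 log2 from levels between 7.75 and 15.5 CPM. The neutrophil chemokine gene Cxcl5 rose from 119 ± 6.08 to 201 ± 5.18 CPM. The call of Il33 was lost without KO replicate 2 (edgeR adjusted p = 0.0509), and those of the other 7 genes were lost without KO replicate 1 and also without KO replicate 2, with edgeR adjusted p between 0.0509 and 0.158. Kcnj15 was also lost without wild type replicate 1 (adjusted p = 0.0559) and Cxcl5 without wild type replicate 2 (adjusted p = 0.0712).

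Clec3b, which encodes tetranectin and is a FAP marker, fell from 53.8 ± 0.166 to 20.9 ± 0.315 CPM, a log2 fold change of -1.36 (SE 0.07, edgeR quasi-likelihood adjusted p = 0.00269). Among changed genes of at least 5 mean CPM, Syt13 had the most negative fold change, -1.90 log2 (SE 0.20), from 13.8 ± 0.362 to 3.70 ± 0.830 CPM. Nlrc5, a transactivator of MHC class I genes, and Apol6 followed at -1.42 and -1.40 log2. Phgdh, the first enzyme of serine synthesis, fell from 94.0 ± 3.94 to 51.2 ± 3.10 CPM, and the kinase anchor gene Akap12 from 397 ± 31.7 CPM to 187 and 225 CPM in the KO libraries. Lars2, the mitochondrial leucyl-tRNA synthetase gene, fell by 0.91 log2 from 2538 ± 45.4 CPM. AA474408, Gas2 and Trim30d fell by 1.03, 0.89 and 0.87 log2, and the counts of Trim30d, Apol6 and Lars2 are uncertain, the first 2 because family members can share reads and Lars2 because it is known to hold sequence like that of ribosomal RNA. The calls of these 10 genes were lost without KO replicate 1 (edgeR adjusted p from 0.0603 to 0.15) and without KO replicate 2 (0.0509 to 0.19). Without wild type replicate 2 that of Clec3b was kept and the other 9 were lost (0.0545 to 0.134), and without wild type replicate 1 those of Syt13, Nlrc5, Apol6, Akap12, Lars2 and Gas2 were lost (0.0559 to 0.101).

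**Figure D1:**
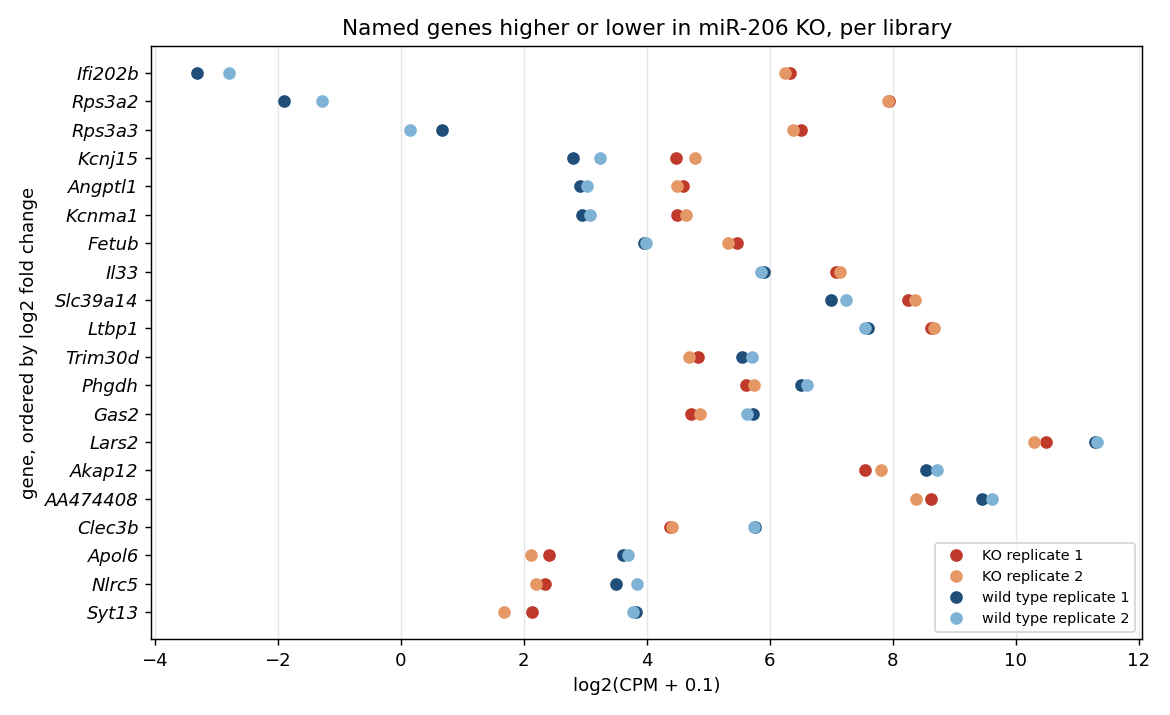
Level of each of the 20 genes with the largest positive or negative fold changes under the naming rule, as log2(CPM + 0.1) on the horizontal axis, with a point per library. The KO points of Ifi202b and Rps3a2 lie far to the right of the wild-type points, and in each of the 20 genes both KO libraries lie on the same side of both wild-type libraries.

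In all, 62 of 14507 genes changed, 35 higher and 27 lower in KO, and 25 of them by at least 2-fold (16 higher, 9 lower). Before adjustment 2080 of the 14507 had an edgeR p under 0.05, which is the share to set beside the unadjusted counts below. In positions, Ifi202b lies on chromosome 1 from 173962568 to 173982744, Rps3a2 on chromosome 14 from 88123017 to 88123808, Rps3a3 on chromosome 13 from 108670603 to 108671397, Il33 on chromosome 19 from 29925114 to 29960718 and Clec3b on chromosome 9 from 123150946 to 123157432. In each fit without a library, which leaves 1 library in a genotype, most of the 62 were not called. Such fits have less power, so a lost call does not show that the call rested on that library. Rps3a1 was not called in any of them. Its log2 fold change was still -0.74, -0.64, -0.74 and -0.64 without KO replicates 1 and 2 and wild type replicates 1 and 2. The uncalled muscle-lineage gene Des moved far, with -3.91, -0.85, -1.17 and -2.07 in the same order. The count was 660 with DESeq2, 491 with no low-count filter and 11 without robust estimation. The main fit called 17.9% false genes among its calls on simulated counts.

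Adipocyte genes were lower in both KO libraries. Of 32 tested adipocyte lipid genes, each had a negative fold change, with a median of -1.24 log2. The wild-type libraries also differed, with a median of 0.89 log2 for replicate 1 over 2, and the muscle-lineage list had a like gap of 0.84. Of the 32 genes, 31 had both KO libraries below both wild-type libraries, where chance gives 16.7% and 24.4% of all tested genes did. The lipid droplet genes Plin2 and Cidec fell, Plin2 from 172 ± 4.29 to 113 ± 0.301 CPM and Cidec from 3.58 ± 1.61 to 0.230 ± 0.00170 CPM, and adjusted over the list alone 2 members fell as well. Both calls were lost without KO replicate 1, KO replicate 2, wild type replicate 1 and wild type replicate 2 in turn, with edgeR adjusted p from 0.0581 to 0.193. Members called numbered 0 without either KO library, 1 without wild type replicate 1 and 4 without wild type replicate 2, and the median without wild type replicate 1 was -0.71. Adipoq, the adiponectin gene, had 9.68 ± 4.44 CPM in KO and 65.7 ± 40.0 in wild type, and Fabp4 had 31.2 ± 11.5 against 130 ± 73.4, neither past the threshold. Pparg, the master regulator of adipogenesis, had 8.23 ± 0.524 against 23.1 ± 6.99 CPM (edgeR quasi-likelihood adjusted p = 0.0745). The list was called lower by camera (adjusted p = 2.7e-13), but not with an estimated correlation (adjusted p = 0.71 with an estimated correlation).

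Interferon-stimulated genes were also lower. Of 36 tested, 34 had negative fold changes, with a median of -1.01 log2; 1 fell over all genes, and adjusted over the list alone 23 fell and 1, Ifi27, rose. Rtp4 fell from 85.0 ± 9.72 to 48.0 ± 1.97 CPM, a log2 fold change of -0.83 (SE 0.10, edgeR quasi-likelihood adjusted p = 0.0375). Ifit1 had 118 ± 22.9 CPM in KO and 307 ± 66.6 in wild type. The call by camera (adjusted p = 3.2e-14) was lost with the other setting (adjusted p = 0.71 with an estimated correlation). The call of Rtp4 was lost without KO replicate 1, KO replicate 2 or wild type replicate 2 (edgeR adjusted p of 0.159, 0.156 and 0.0712), and 0 members fell in those 3 fits, against 17 without wild type replicate 1.

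Muscle-lineage genes set KO replicate 2 apart from the other libraries. The embryonic myosin gene Myh3 had 447 CPM in KO replicate 1, 51.5 in KO replicate 2, and 822 and 507 in the wild-type libraries, and skeletal actin, Acta1, had 424, 50.4, 782 and 457. The 34 tested members had a median of -1.46 log2 and 0 of them changed by edgeR, over all genes or adjusted over the list alone; 1 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. Without KO replicate 2 the median was -0.66, and without KO replicate 1 it was -3.70. The list was called lower by camera (adjusted p = 3.6e-07; adjusted p = 0.72 with an estimated correlation). As in the adipocyte and interferon lists, both KO libraries had a lower median than the wild type.

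**Figure D2:**
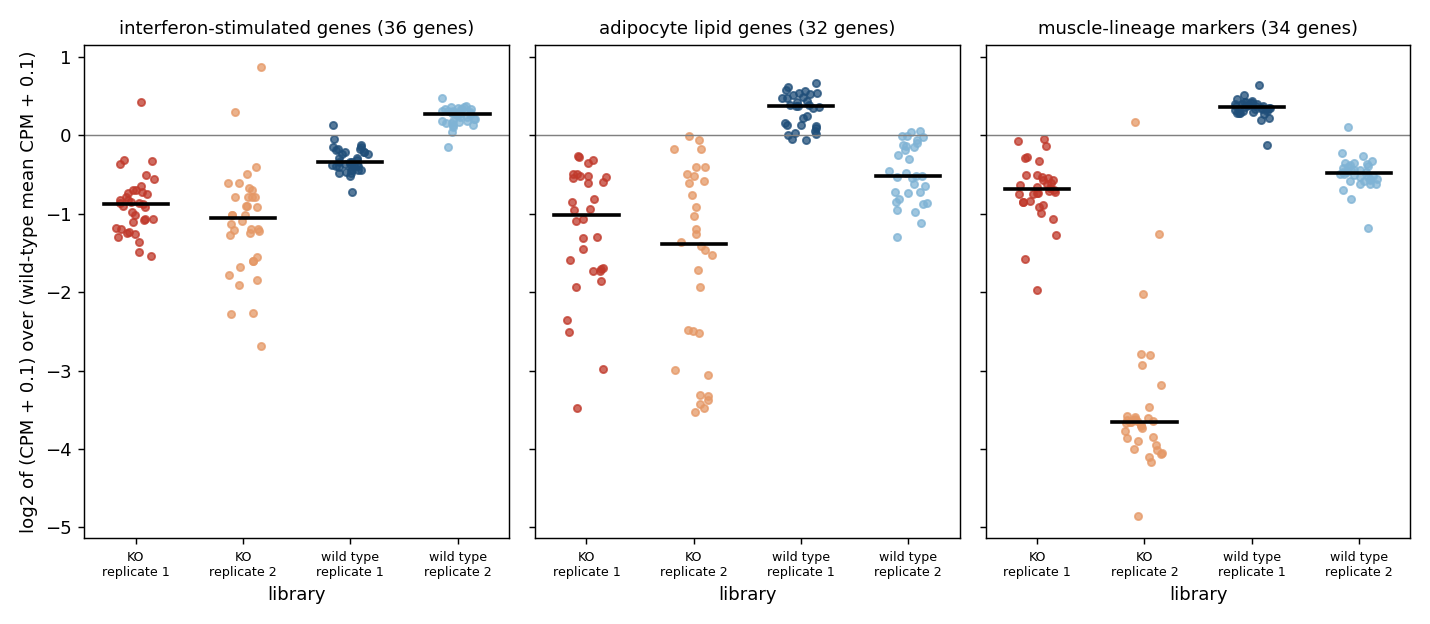
Each gene of the interferon-stimulated, adipocyte lipid and muscle-lineage lists in each of the 4 libraries, as the log2 ratio of its CPM + 0.1 to the wild-type mean CPM + 0.1, with points for genes and black bars for medians. The medians of KO replicate 1 and 2 are -0.87 and -1.05 for the interferon list, -1.01 and -1.39 for the adipocyte list, and -0.68 and -3.65 for the muscle-lineage list, and those of wild type replicate 1 over 2 are -0.62, 0.89 and 0.84 in the same order.

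Camera called 14 of the 33 lists, 4 higher and 10 lower. With an estimated correlation 0 were called, and 0 had an unadjusted p under 0.05. That setting takes its degrees of freedom from the 4 libraries and not from the genes, so it has little power here. A call lost by it need not reflect correlation among genes. In the Wnt, histone and Notch lists the estimated correlation was below 0 (-0.009, -0.035 and -0.013). Their unadjusted camera p still went from 0.0036, 0.0028 and 0.0071 to 0.077, 0.09 and 0.1. By fry's directional test, 0 were called and 5 had an unadjusted p under 0.05. Fry's test for change in either direction had an adjusted p under 0.05 in more lists, from 0.0024 to 0.048. Of the lists called by camera these were senescence, basement membrane, histone, fibrillar matrix, glycolysis and Notch genes. Of the uncalled lists they were FAP identity, osteogenic, cytokine, TGF-beta and BMP, stress response and reported target genes and the Mir206 neighbours. In 26 lists 0 members changed over all genes by edgeR; 130 of their members had an unadjusted p under 0.05, DESeq2 called 55 and limma-voom 1. Senescence and p53 targets were lower (adjusted p = 2.1e-04; adjusted p = 0.71 with an estimated correlation; median -0.31 log2), with 0 of 21 members changed over all genes and 9 that fell adjusted over the list alone. The median was -0.17 without KO replicate 1, and Cdkn1a, the p21 gene, had 189 ± 10.1 CPM against 304 ± 44.6. Basement membrane genes were lower (adjusted p = 0.008; adjusted p = 0.71 with an estimated correlation), with 0 of 18 members changed and 5 that fell adjusted over the list alone, and Nid1 and Col4a1 had log2 fold changes of -0.15 and -0.36. Of 9 nucleosome histone genes, whose near-identical copies can share reads, Hist1h2bc fell by 0.86 log2, a call lost in each fit without a library (edgeR adjusted p from 0.0559 to 0.139), and 2 fell adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.71 with an estimated correlation). Fibrillar matrix genes were higher (adjusted p = 0.0028; adjusted p = 0.72 with an estimated correlation), with 0 of 35 changed and 5 that rose adjusted over the list alone. Col3a1 and Fn1 had log2 fold changes of 0.27 and 0.36, and the call was lost without KO replicate 1 (adjusted p = 0.14).

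The other called lists had medians between -1.13 and 0.20 log2, and 0 of their members changed over all genes. Wnt pathway, contractile and myofibroblast, and glycolysis and hypoxia genes were higher, with 1, 2 and 2 members that rose adjusted over the list alone. Cell cycle, Notch pathway and cholesterol synthesis genes and the 3 tested keratinocyte and epithelial markers were lower; adjusted over the list alone, 1 Notch pathway member rose and 0 members of the other 3 lists changed. Their adjusted p lay between 0.71 and 0.76 with an estimated correlation, and Top2a and Pcna of the cell cycle list were at -0.10 and 0.00 log2, with Pcna below 0 under library size alone. The Wnt call was lost without KO replicate 2 (adjusted p = 0.18) and the contractile call without KO replicate 2 or wild type replicate 2 (0.21 and 0.059). The glycolysis call was lost without KO replicate 1 or wild type replicate 2 (0.31 and 0.21). The Notch call was lost without KO replicate 2 or either wild-type library (0.081, 0.16 and 0.051). The keratinocyte call was lost without either KO library (0.21 and 0.081). The cell cycle call was lost without KO replicate 1 (0.21) and turned to the higher side without wild type replicate 2 (0.92). The cholesterol call turned to the higher side without KO replicate 1 (0.9) and was lost without wild type replicate 2 (0.58).

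The FAP identity list was not called by camera, and its members went both ways: Clec3b fell, and adjusted over the list alone 6 members rose and 5 fell. Of its 23 tested members 13 had an unadjusted p under 0.05 by edgeR and DESeq2 called 11. Fry's test for change in either direction had an adjusted p of 0.0044. Fry's test does not set this list apart, since other uncalled lists had low values by it. Among them were cytokine and chemokine genes (0.0024), the TGF-beta and BMP list (0.006) and osteogenic genes (0.016). A smaller share of those lists had an unadjusted edgeR p under 0.05, namely 9 of 29, 11 of 34 and 4 of 17 members. DESeq2 called 7, 5 and 3 of them. Over all tested genes 2080 of 14507 had an unadjusted edgeR p under 0.05. Cytokine and chemokine genes were not called as a list, although Il33 and Cxcl5 rose and, adjusted over the list alone, 5 rose and 1 fell. Ltbp1 was the changed gene of the TGF-beta and BMP list and Phgdh that of the unfolded protein and integrated stress response list. Adjusted over the list alone 3 rose and 2 fell in the first, and 2 fell in the second. Of 25 adipogenic transcription factors 0 changed over all genes. Adjusted over the list alone 1 rose, Cebpd (0.45 log2), and 1 fell, Pparg (-1.49 log2). Ebf1 had a log2 fold change of -0.33 and did not pass over the list alone. The lists of anti-adipogenic regulators, osteogenic, chondrogenic and tendon genes, YAP/TAZ targets, complement, pentose phosphate genes, endothelial, hematopoietic, pericyte and glial markers, sex-linked genes and immediate early genes were not called either. Camera adjusted p over the 19 uncalled lists lay between 0.06 and 0.99, with medians from -0.14 to 0.29 log2. Glial markers had a median of 0.06, a mean of -0.16 and a test on the lower side, and endothelial markers a median of -0.04, a mean of -0.01 and a test on the higher side. Without KO replicate 2 the pentose phosphate list was called lower (adjusted p = 0.016), and without wild type replicate 2 the cytokine list was called higher (adjusted p = 0.034).

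No shift of predicted miR-206 targets as a group passed the test. Of 13846 tested genes with an annotated 3' UTR, 2629 held a 7mer or 8mer seed site, with a median log2 fold change of 0.00 against -0.00 in the 11217 without (limma camera adjusted p = 0.84). The 613 genes with an 8mer had a median of 0.00 (limma camera adjusted p = 0.84). Of the genes with a site, 2 rose and 4 fell. The median of site genes over the rest was 0.003 log2, and 17 of 50 control seeds gave one as high. Among 34 tested genes reported as miR-1 or miR-206 targets, 0 changed over all genes by edgeR, 14 had an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 0. Adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.49). Fold changes were positive in 14 and negative in 20, and fry's test for change in either direction had an adjusted p of 0.01. Sfrp1, a Wnt antagonist of that list, had 1987 ± 127 CPM in KO and 1337 ± 209 in wild type, and Fstl1 had 2843 ± 296 against 2831 ± 324. Runx1 had 153 ± 14.1 against 110 ± 24.2 CPM, a log2 fold change of 0.49 (SE 0.17, edgeR quasi-likelihood adjusted p = 0.332), which did not pass the threshold. The simulated fit called 7 of 50 genes changed by 0.5 log2, so the lack of a call says little. The searched 3' UTR of Runx1 held 0 seed sites.

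**Figure D3:**
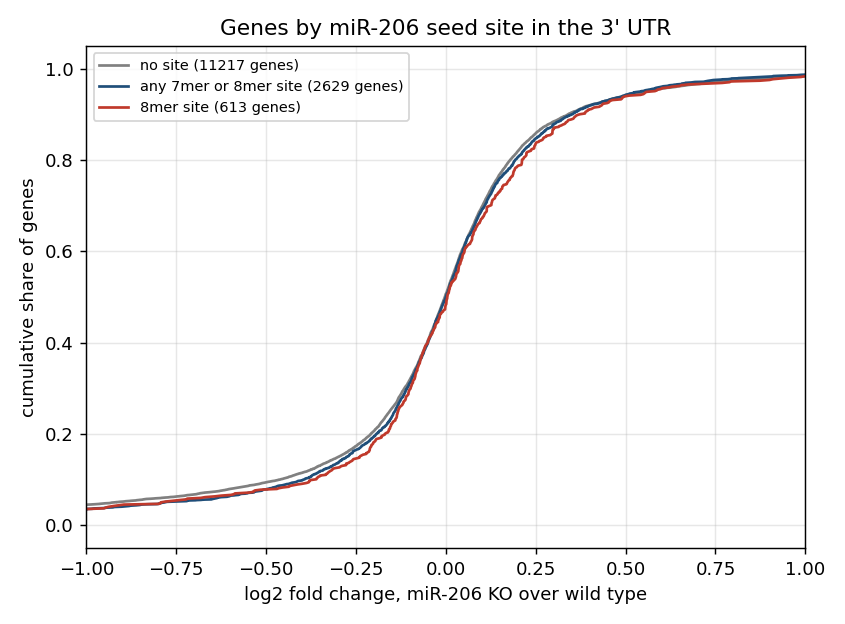
Cumulative share of tested genes by log2 fold change of KO over wild type, for 11217 genes without a miR-206 seed site in the 3' UTR, 2629 with a 7mer or 8mer site and 613 with an 8mer. The horizontal axis is limited to fold changes between -1 and 1, and the 3 curves cross the middle of the vertical axis near 0.

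The neighbours of Mir206 on proximal chromosome 1 were not called as a list by camera. Of 41 tested, 0 changed over all genes by edgeR, 8 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0. Adjusted over the list alone 2 rose (camera adjusted p = 0.13). Fry's directional test was on the higher side, with an unadjusted p of 0.013 and an adjusted p of 0.26. Its test for change in either direction had an adjusted p of 0.0024. Both KO libraries lay above both wild-type libraries in 15 members and below in 8, against 23.8% and 24.4% of all tested genes. Sulf1 had 550 ± 44.8 CPM in KO against 374 ± 29.5 in wild type. The Y-linked genes Ddx3y and Eif2s3y were expressed in both genotypes, with 60.2 ± 5.31 against 61.7 ± 0.243 CPM and 48.7 ± 3.65 against 42.8 ± 0.284 CPM.

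Of the 1675 transcription factors named in the deposited list, 954 were tested and 0 changed by edgeR, over all genes or adjusted over the list alone. Of the 954, 132 had an unadjusted p under 0.05, a share near that of all tested genes (2080 of 14507). DESeq2 called 40 of them, against 660 genes in all, and limma-voom 0. By edgeR 5 were called without wild type replicate 1 and 2 without wild type replicate 2. The 6 with the smallest adjusted p were Stat2, with a log2 fold change of -0.73, and Notch4, Nr1d2, Foxp1, Hivep3 and Meox2, with 1.45, 0.48, 0.60, 0.68 and 0.43. In the authors' deposited table Asb5, Pparg, Asb2 and Ankrd1 had log2 differences of -1.51, -1.51, -1.35 and -1.33. Across 12051 shared genes, which are not independent replicates, Spearman's rho between the authors' deposited table and the edgeR fold changes was 0.898, and 89.8% had the same sign.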

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

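The covariate for muscle-lineage RNA was chosen after the data were seen, and the other settings were planned. The counts of changed, higher, lower and 2-fold changed genes (62, 35, 27 and 25) stayed within 1.5 times with DESeq2 size factors, upper-quartile scaling, a filter at 5 CPM and limma-voom. They were 133, 62, 71 and 54 with library size alone, 491, 273, 218 and 109 with no low-count filter, and 660, 321, 339 and 185 with DESeq2. With limma on log2(TPM + 1) and on log2(TPM + 0.1) they were 6, 4, 2 and 6, and without robust estimation 11, 9, 2 and 10. With the muscle-lineage covariate they were 356, 189, 167 and 123. The cause was not tested for any of these. Muscle-lineage genes had lower medians in both KO libraries, so the covariate overlaps with genotype. Its added term also leaves fewer residual degrees of freedom than the main fit has. Leaving out each library in turn, where the lone library is assumed to vary like the other group, gave 7 to 77 changed, 6 to 27 higher, 1 to 56 lower and 7 to 51 changed 2-fold. With the replicate number as a block, the paired fit called 265, 126, 139 and 92 genes and 23 transcription factors. That fit too has fewer residual degrees of freedom than the main fit. The same-numbered libraries share only a number, and their deviations correlated at 0.187 across genes. Depth was not varied; with 2 libraries per genotype, the simulated fit called 7 of 50 genes changed by 0.5 log2.

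Called lists numbered 14, and 0 with an estimated correlation or by fry, and 9 to 13 without a library. With the muscle-lineage covariate 12 were called: the contractile, Wnt, Notch, keratinocyte and muscle-lineage calls were lost, and chondrogenic, pentose phosphate and stress response genes were called. Of the 14, 6 kept their call and direction in 4 of the 4 fits without a library, namely adipocyte, interferon, muscle-lineage, senescence, basement membrane and histone genes. DESeq2 called 40 transcription factors, and fits without a library 0 to 5. The seed site test, with an unadjusted camera p of 0.84, had values between 0.44 and 0.89 without a library, and turned to the lower side by fry, with a p of 0.88, and without KO replicate 2, with 0.89. Spearman's rho with the authors' table was 0.905 over genes of at least 5 mean CPM.

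Genes that changed sign were not called in any such fit. Axl (0.02 log2) was at -0.021 with library size alone, -0.035 with both TPM fits, -0.13 with the covariate and -0.13 to 0.18 without a library. Pcna was at -0.035 with library size alone, -0.001 at 5 CPM, -0.06 with the covariate and -0.06 to 0.068 without a library; Fstl1 was at -0.03 with library size alone, -0.18 with the covariate and -0.11 to 0.13. Rbpj was at 0.002 with upper-quartile scaling, 0.071 with the covariate and -0.073 to 0.053 without a library. With the covariate Actg1 was at -0.18, Myh3 at 0.13, Acta1 at 0.18 and Ddx3y at 0.08. Ranges without a library were -0.092 to 0.32 for Actg1, -0.28 to 0.72 for C3, -0.13 to 0.054 for Ddx3y, -0.28 to 0.002 for Hmgcs1, -0.25 to 0.03 for Pdgfrb, -0.16 to 0.048 for Srebf2 and -0.29 to 0.13 for Top2a.

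Lists that changed direction were uncalled there. Adjusted p was 0.98 by fry for FAP identity. With the covariate it was 0.34 for muscle-lineage genes, which define that covariate, and 0.42 for glial markers. With no filter it was 0.96, 0.46 and 0.88 for endothelial, hematopoietic and glial markers, with the block 0.94 for endothelial and 0.91 for glial markers, and with library size alone 0.96 for glial markers. Ranges without a library were 0.31 to 0.97 for anti-adipogenic, 2.4e-07 to 0.92 for cell cycle, 4.3e-06 to 0.9 for cholesterol, 0.064 to 0.94 for chondrogenic, 0.052 to 0.73 for complement and 0.13 to 0.95 for osteogenic genes. They were 0.34 to 0.92 for endothelial, 0.69 to 0.88 for glial, 0.47 to 0.97 for hematopoietic and 0.29 to 0.9 for sex-linked genes.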

Other observations

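Further called genes and the Hox genes below were chosen after their values were seen, as were the tests of muscle-lineage cells, of adipocytes, of the Rps3a copies and of DNA beside Mir206; the tests of position across the genome and of other splits were written before their results. Both chains of the type 2 interleukin 4 and 13 receptor rose in KO cells: Il4ra from 169 ± 12.2 to 314 ± 19.4 CPM and Il13ra1 from 78.4 ± 5.01 to 143 ± 9.28 CPM. Tgm2, which cross-links matrix proteins, rose by 0.90 log2, and Nox4 and Sod3, which make and remove reactive oxygen species, rose by 0.81 and 0.78 log2. Without KO replicate 1, KO replicate 2 or wild type replicate 2, these 5 genes were not called (edgeR adjusted p from 0.0514 to 0.14), and without wild type replicate 1 Tgm2 was called and Il4ra, Il13ra1, Nox4 and Sod3 were not (0.052 to 0.146). Of 29 Hox genes, which mark body position, with at least 1 CPM, 22 had positive and 7 negative fold changes. By edgeR 0 of them were called and 8 had an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0. Hoxd13, Hoxb3 and Hoxc8 had log2 fold changes of 1.83, 1.13 and 0.64, and Hoxc13 and Hoxa11 had -0.72 and -0.37.

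Muscle-lineage genes were low in KO replicate 2. Over 30 members of at least 5 CPM the median log2 ratio of KO replicate 2 to KO replicate 1 was -3.08 (quartiles -3.35 and -3.01), and 30 of 30 were lower, including Myh3 at 51.5 against 447 CPM and Acta1 at 50.4 against 424. A genotype effect alike in both KO libraries would give a ratio near 0, and -3.08 argues against it as the whole cause. An unequal number of muscle-lineage cells in the cultures remains a candidate explanation and gives the shared ratio, although sorting for Sca1 should remove such cells. A genotype effect on their number stays open and untested, since KO replicate 1 lay below both wild-type libraries in 23 of the 30; of the 36 listed markers, 2 are also among the reported targets and 1 among the pericyte markers.

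Adipocyte genes were lower in both KO libraries. Without KO replicate 2 the median of the list was -1.02 log2, with 32 of 32 members negative. This argues against the missing muscle-lineage RNA of that library as the only cause. KO replicate 1 also lay below the wild type in muscle-lineage genes, with a median of -0.65 log2. Both lists had lower medians in KO replicate 2 than in KO replicate 1 and in wild type replicate 2 than in wild type replicate 1. A difference among libraries common to both lists is therefore not covered by leaving out KO replicate 2. Resampling list members gave a bootstrap 95% interval of -1.59 to -0.60, but members are not independent. The interval carries no spread between libraries, and the wild-type libraries alone differed by a median of 0.89 log2. Over 27 members of at least 5 CPM, the ratio of wild type replicate 1 to 2 had a Spearman's rho across genes, which are not independent, of 0.80 with the ratio of wild type replicate 2 to KO; the shared library enters with opposite signs, and 1000 draws of other genes of like level had a median of -0.20 (95% between -0.61 and 0.23). A lower share of adipocytes in the KO cultures is a candidate explanation, as is lower activity of the adipocyte program in each cell, which was not tested. Whether the genotype or the culture set that share stays open with 2 libraries per genotype.

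A few genes were near on or off by genotype. The summed CPM of Rps3a1, Rps3a2, Rps3a3 and Gm10020 was 897 ± 32.1 in KO and 837 ± 40.8 in wild type, a log2 ratio of 0.10. Shared reads divided differently between the genotypes are therefore a candidate explanation for those 4 genes, although their sequences were not compared. DNA carried along beside Mir206 does not account for the pattern as a whole, since 0 of the 8 called genes beyond 3 log2, and 0 of 62 called genes, lay within 20 Mb of Mir206, where 134 genes were tested. Blocks of another strain's genome elsewhere cannot be told apart from chance by position: 10 called genes lay within 1 Mb of another, and a share of 0.141 of 1000 random draws had as many. The 10 included overlapping protocadherin genes. They also included Rps3a1 and Cd1d2 on chromosome 3, from 86137940 and 86986551, so a strain block stays open for that pair. The others were Clec3b with Lars2, Fetub with Rtp4, and Gm2260 with Gm9780. A strain variant may still underlie Ifi202b and Cd1d2, whose levels are known to differ between inbred strains, as the wild type is C57Bl/6 and the background of the KO mice is not given in the labels.

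The 4 libraries can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The genotypes gave 62 calls and were the 1 split with that many, and the highest of the other splits gave 0. Each other split puts a KO and a wild-type library in each group. A difference between the genotypes then widens the spread within groups and lowers the calls, so the 0 does not measure what chance gives.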
